A study of Arabidopsis thaliana with 24 samples.

How the data were processed

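RNA was extracted with TRIZOL from whole 14-day-old seedlings of Arabidopsis thaliana Col-0 and its derived lines, and libraries were made with the Lexogen SENSE mRNA-Seq kit, per the labels. The labels call the replicates biological triplicates; where plants were grown together is not stated further, so p-values measure the spread between these samples only. Per the submitters' processing notes bcl2fastq 2.17.1.14, HISAT2 2.1.0, HTSeq, DESeq2 and genome build TAIR10 were used, with the role and order of the tools not given in the sources used here. The annotation release and the strand setting of read counting are not given either, so genes that overlap a gene on the opposite strand have uncertain values; those printed are AT1G64795, AT1G64580, RLP23, MRD1, LEA7, AT3G29631, CDKB2;1, CDKB2;2, PCNA2, AUR1, LHCB4.2, PAP17, CSD1, FLC, SPL15, RRP44A, RH6, OLEO2, BCAT4, PSAG, F3H, ARF5, GRF1, SPL3 and DCL3. PSAD2, AT1G66100 and AT1G04533 overlap a gene on the same strand.

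The deposited table holds a signal per gene and library that the authors made as read counts divided by a size factor per library, with DESeq2 1.24.0 per the file header. Every value was a whole multiple of a single step per library within a tolerance of 1e-06, so whole reads were recovered for all 24 libraries; in 3 of them the step was 1.005, 1.008 and 1.009. Size factors were set separately for the 2018 and 2019 libraries, which list different genes: 1208 and 660 of 27782 genes are missing. The table also holds log2 fold changes that the authors deposited from DESeq2 for dne1, the DNE1 overexpressors, the D153N line and vcs, each against WT. Beside them stand the p-values, adjusted ones from the authors' DESeq2 per the file header; both kinds of column were set against the results here and used for nothing else. Of the gene identifiers 27574 matched the reference annotation TAIR10.1, which gave symbols, descriptions, transcript lengths, GC content and overlaps; no coordinates are printed. A transcript's shared sequence is the percent of its words of 31 bases that occur in other transcripts, and genes with over 20% were taken as uncertain.

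Genes were tested with limma 3.58.1 (trend, R 4.3.3) on log2 of the normalized count plus 1, two-sided, among genes with a normalized count of at least 10 in at least 3 libraries, and called at a Benjamini-Hochberg adjusted p under 0.05. The edgeR quasi-likelihood test with TMM factors had been written down for raw counts before the data were examined; since the table holds normalized values, limma replaced it, and edgeR on recovered reads became an alternative once the unit was known. The 12 libraries of batches 1 to 3 were fitted together, the 6 of each later line with its own WT separately, and the differences of effects in a fit of all 24 libraries with 8 groups. The test of both DNE1 overexpressors together was added after the data were seen. Alternatives were DESeq2 1.42.0 and edgeR 4.0.16 on recovered reads (with RLE factors, which are the deposited kind of scaling, with library size only, and with TMM), other filters, a minimum log2 change of 1, the batch as a block, other sets of libraries, and every library left out in turn. Pseudocounts of 0.5 and 5, TMM factors for gene lists and shared calls, removal of each library's trend on length and GC content, and batches 1 and 2 alone were chosen after seeing the data.

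Batch numbers pair the libraries of batches 1 to 3 and 7 to 9. Deviations from group means correlated across genes at 0.14 to 0.68 for 18 pairs of libraries of the same batch and at -0.58 to 0.22 for 36 pairs of different batches in batches 1 to 3, and at 0.07 to 0.23 (3 pairs) and -0.33 to 0.17 (6 pairs) in batches 7 to 9. The deposited columns of vcs-6 carry no batch, so no block was fitted for it.

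The 23 gene lists, the comparisons, the first set of alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists of a comparison, with the estimated correlation given beside each call. By the rule, DNE1 and VCS are named everywhere, with the 8 largest rises and falls per comparison with WT among called genes with the same sign in all 3 batch pairs and a mean CPM (reads scaled to library size) of at least 1, up to 4 members per list, and the 5 largest in each direction for differences of effects. The text prints a part of these. For vcs-6 every line library had to lie on the same side of every WT library in place of the pairs. Where a group of a comparison or of a difference of effects holds 3 or fewer reads, no fold is given. Shared calls were tested with Fisher's exact test, two-sided.

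On simulated data with 200 genes changed, the procedure was tested for calls of true and false changes in every design. Tests of explanations were written down before the measured result for 1 of them only, the photosynthesis genes after removal of the length and GC trend; all others were written after it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.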

Results

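Messenger RNA was sequenced from whole 14-day-old Arabidopsis thaliana seedlings in 24 libraries that fall into 8 groups of 3. DNE1 (AT2G15560) and VARICOSE (VCS, AT3G13300), a scaffold of the mRNA decapping complex, are the genes the lines alter. Batches 1 to 3, labelled 2018, held wild-type Col-0 (WT), a dne1 insertion mutant and a pair of lines, OE1 and OE2, that overexpress a GFP fusion of DNE1 from the 35S promoter of cauliflower mosaic virus. Batches 4 to 6, labelled 2019, held WT and libraries labelled vcs-6. Batches 7 to 9, also labelled 2019, held WT and a line overexpressing a GFP fusion of DNE1 with the D153N substitution. Recovered reads per library ran from 36714564 to 70561391 in the 2018 libraries and from 22611653 to 53908600 in the 2019 libraries. The labels call the 3 replicates of a group biological. Levels below are normalized read counts as mean ± SD with n = 3 libraries per group, changes are log2 ± SE, and adjusted p is limma's value with Benjamini-Hochberg adjustment over all genes tested.

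DNE1 and VCS transcripts were examined first, since they bear on the labels. DNE1 stood at 1462 ± 146 in WT of batches 1 to 3 and fell by 2.25 ± 0.14 to 309 ± 50.1 in dne1 (adjusted p = 0.00012). It rose to 21230 ± 2140 in OE1, to 19980 ± 2010 in OE2 and, from 819.7 ± 29.6 in its own WT, to 15780 ± 3210 in the D153N line. VCS did not follow the label of its mutant: it rose by 0.62 ± 0.12, from 5282 ± 600 in WT to 8115 ± 632 in the libraries labelled vcs-6 (adjusted p = 0.0041). A read count over the whole gene does not show whether a transcript is intact, so it does not check that label, and these libraries are called the libraries labelled vcs-6; where counts are listed, vcs-6 alone stands for them. VCS fell by 0.51 ± 0.08 in the D153N line (adjusted p = 0.013) and was called in none of dne1, OE1 and OE2.

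**Figure D1:**
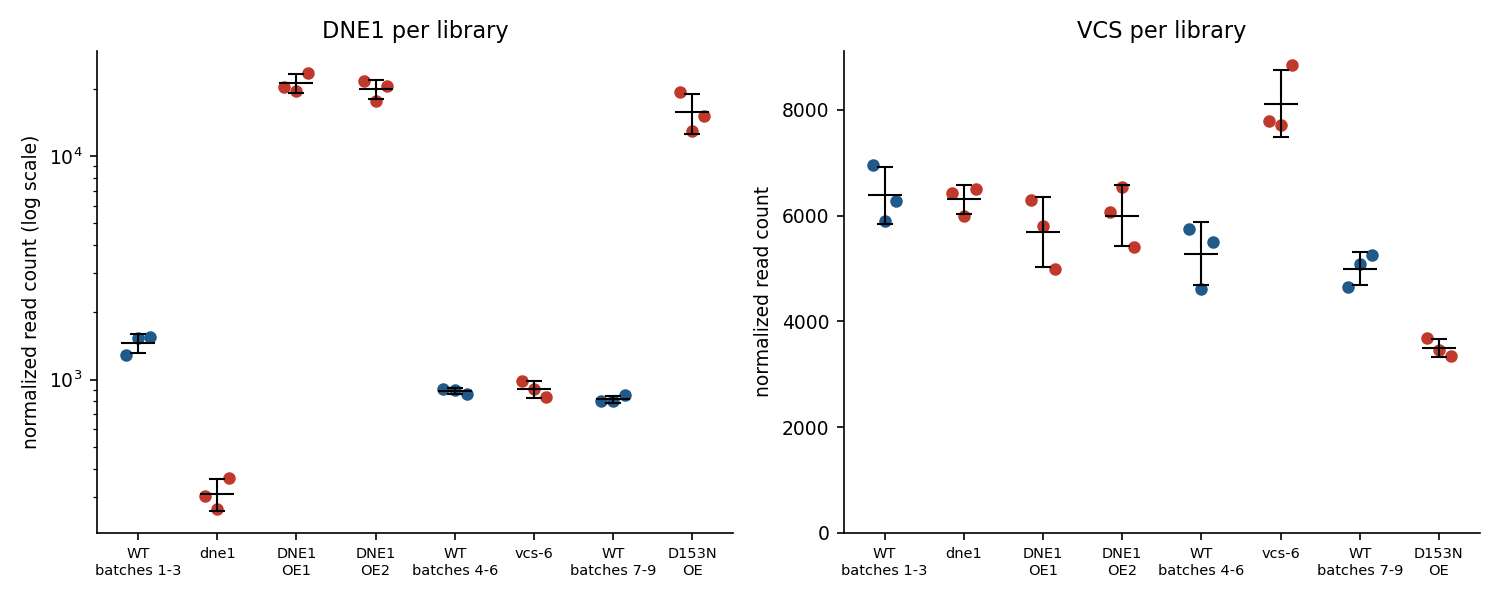
Normalized read counts of DNE1 (left, log axis) and VCS (right, linear axis) in each of the 24 libraries, by group; blue points are WT, red points the lines, and the black bars give mean and SD of 3 libraries. DNE1 lies at 263 to 362 in dne1 and at 12986 or more in every overexpressor library, and VCS lies at 7719 to 8844 in the libraries labelled vcs-6. Batches 1 to 3 were scaled separately from batches 4 to 9, so levels are not directly comparable between these sets.

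The first comparison asked what loss of DNE1 changes in the seedling. Besides DNE1, 3 genes passed the test in dne1. ARP9 (AT5G43500), an actin-related protein, rose from 1336 ± 108 to 2968 ± 550 (adjusted p = 0.046). AT1G64795 rose from 11.4 ± 11.5 to 802 ± 130 (adjusted p = 0.045) and the noncoding RNA AT4G04223 fell from 606.9 ± 173 to 69.5 ± 9.77 (adjusted p = 0.00039). AT1G64795 overlaps a gene on the opposite strand and AT4G04223 shares 50.1% of its 31-base words with other transcripts, so reads of both may be divided between loci; their values are uncertain. AT4G04223 also stood at only 28.2 to 38.6 in the 6 WT libraries of 2019.

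In all, 4 of 21631 genes were called in dne1, 2 higher and 2 lower, and 352 had an unadjusted p under 0.05. DESeq2 called 7 genes. The count was 7 without WT library 2, and 2 without dne1 library 2, WT library 3 or dne1 library 3. Of the 23 gene lists fixed before the data were examined, 4 were called by camera, though no member of any of them passed the gene test, in the fit or adjusted over the list alone. Genes of abscisic acid, cold and drought responses lay higher (median 0.16, adjusted p = 0.023, and adjusted p = 0.86 with an estimated correlation), as did deadenylation, exosome and nonsense-mediated decay factors (median 0.05, adjusted p = 0.032, and adjusted p = 0.63 with an estimated correlation). Flowering and floral organ markers lay lower (median -0.56, adjusted p = 0.012, and adjusted p = 0.86 with an estimated correlation), and so did photosynthesis genes (median -0.18, adjusted p = 0.032, and adjusted p = 0.86 with an estimated correlation). With the batch as a block the deadenylation call was lost (adjusted p = 0.051) and the iron deficiency list was called lower (adjusted p = 0.0029). With library size as the only scaling the abscisic acid call was lost (adjusted p = 0.053), and iron deficiency (adjusted p = 0.015), rapid touch (adjusted p = 0.0041) and seed storage (adjusted p = 0.015) lists were called lower. Median and mean differed in sign for the root list (-0.08 and 0.04) and the small RNA list (0.03 and -0.02).

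Overexpression of DNE1 was asked about in both lines, each against the same 3 WT libraries. Receptor genes were among the largest rises. CRK23 (AT4G23310), a cysteine-rich receptor-like kinase, rose from 3.45 ± 4.34 to 63.3 ± 21 in OE1 and to 62.7 ± 4.91 in OE2. RLP23 (AT2G32680), a receptor-like protein, rose to 318 ± 135 in OE2 from 16.2 ± 12.4 (4.37 ± 0.63, adjusted p = 0.03). FLA5 (AT4G31370), a fasciclin-like arabinogalactan protein, rose by 3.80 ± 0.32 in OE2 (adjusted p = 0.00053). AT3G42090 rose from 2.93 ± 2.46 to 255.8 ± 27.7 in OE1 and 241 ± 40.4 in OE2. Among the falls, the amino acid permease gene AAP2 (AT5G09220) fell by 0.85 ± 0.14 and IMS2 (AT5G23020), of glucosinolate chain elongation, fell by 0.95 ± 0.15 in OE1. A gene given here or below for a single line is not shown to differ between the lines. Limma called 0 genes for OE1 against OE2.

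OE1 had 30 called genes of 21631, 24 higher and 6 lower, and OE2 had 37, 32 higher and 5 lower. With the batch as a block the counts were 268 (222 higher, 46 lower) and 253 (212 higher, 41 lower), and DESeq2 called 200 and 168. Both lines tested together against WT gave 79 genes, 72 higher and 7 lower; the block gave 534 and DESeq2 329. AT1G64795 rose in OE1 and OE2 as in dne1, and was also called higher in the libraries labelled vcs-6 (adjusted p = 1.9e-05) and in the D153N line (adjusted p = 0.003), so its change does not follow the level of DNE1. AT4G04223 fell in both OE1 and OE2; the copies and overlaps named above apply. SESA2 (AT4G27150), a seed storage albumin, rose from 0.659 ± 0.612 to 106 ± 67.8 in OE2 (adjusted p = 0.028). CRK6 (AT4G23140), which rose by 3.79 ± 0.58 in OE2, shares 31.7% of its 31-base words with other transcripts, and RLP23 has a gene on the opposite strand.

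Single libraries moved these counts. In OE1 the count was 11 without WT library 1, 10 without OE1 library 1, 11 without OE1 library 2, 15 without WT library 3 and 10 without OE1 library 3. In OE2 it was 10 without WT library 1, 5 without OE2 library 1, 5 without OE2 library 2, 16 without WT library 3 and 8 without OE2 library 3. For both lines together it was 14 without WT library 1, 23 without WT library 3, 44 without OE1 library 2, and 36, 35 and 45 without OE2 libraries 1, 2 and 3. Of 11 values named for OE1 and 12 for OE2, 8 each lost their call when a single library was left out, CRK23, RLP23 and AAP2 among them. These fits had no batch block. With the block and all libraries 0 values lost their call in either line, while edgeR with RLE factors lost 5 in OE1 and 6 in OE2.

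Gene lists called in the overexpressors held no member past the gene test in the fit without the batch block. The authors' deposited DESeq2 comparison of the overexpressors did call some members. Among them were SEP3 (adjusted p = 5.67e-10), KIN1 (adjusted p = 7.54e-15) and AT4 (adjusted p = 0.000326), while others such as SPX1 (adjusted p = 0.803) were not called. Phosphate starvation genes lay higher in OE1 (median 0.44, adjusted p = 0.0025, and adjusted p = 0.65 with an estimated correlation) and in OE2 (median 0.55, adjusted p = 1.9e-05, and adjusted p = 0.17 with an estimated correlation); adjusted over the list alone, 3 and 2 members passed. Cell cycle and shoot meristem genes lay higher by a median of 0.22 in OE1 (adjusted p = 0.0064, and adjusted p = 0.92 with an estimated correlation) and of 0.26 in OE2 (adjusted p = 3.9e-05, and adjusted p = 0.54 with an estimated correlation). Flowering markers were called higher (adjusted p = 0.035 and 0.00024, and adjusted p = 0.92 and 0.53 with an estimated correlation), and glucosinolate genes likewise (adjusted p = 0.037 and 0.00067, and adjusted p = 0.92 and 0.62 with an estimated correlation). The rapid touch and wound list lay lower in OE1 (median -0.64, adjusted p = 0.00031, and adjusted p = 0.92 with an estimated correlation) and in OE2 (median -1.07, adjusted p = 0.049, and adjusted p = 0.94 with an estimated correlation).

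OE2 alone had called lists for heat shock (median 0.66, adjusted p = 5.6e-05, and adjusted p = 0.53 with an estimated correlation), abscisic acid (median 0.52, adjusted p = 4.9e-05, and adjusted p = 0.7 with an estimated correlation) and jasmonate (median 0.33, adjusted p = 0.019, and adjusted p = 0.72 with an estimated correlation). Adjusted over the list alone, 1 heat shock and 1 abscisic acid member passed. The block added abscisic acid (adjusted p = 0.036) and photosynthesis (adjusted p = 0.0023) to the lists called higher in OE1. In OE2 it added photosynthesis (adjusted p = 0.00099) and ended the touch call (adjusted p = 0.085). With library size only photosynthesis was called higher in OE1 (adjusted p = 0.039) and OE2 (adjusted p = 0.022). Median, mean and test differed in sign for anthocyanin, circadian, ethylene and miRNA target lists in OE1 and for circadian, ethylene, miRNA target, seed and small RNA lists in OE2.

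Both lines tested together had 7 called lists. These were phosphate starvation (adjusted p = 0.00013, and adjusted p = 0.26 with an estimated correlation; 5 members adjusted over the list alone), cell cycle (adjusted p = 0.00025, and adjusted p = 0.66 with an estimated correlation; 1 member), flowering (adjusted p = 0.0021, and adjusted p = 0.66 with an estimated correlation; 1), glucosinolate (adjusted p = 0.0025, and adjusted p = 0.75 with an estimated correlation), heat shock (adjusted p = 0.0025, and adjusted p = 0.62 with an estimated correlation; 1) and abscisic acid (adjusted p = 0.0025, and adjusted p = 0.96 with an estimated correlation; 1), all higher. The touch list lay lower (adjusted p = 0.0021, and adjusted p = 0.82 with an estimated correlation). With the block the iron (adjusted p = 0.041) and photosynthesis (adjusted p = 0.00057) lists were called as well, and with library size only photosynthesis was (adjusted p = 0.015). Circadian, ethylene, miRNA target, root and small RNA lists differed in sign between median, mean and test.

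OE1 and OE2 were then set against each other. DNE1 itself differed by 0.09 ± 0.14 (adjusted p = 1) and VCS by -0.08 ± 0.12. Limma called 0 of 21631 genes, with 152 at an unadjusted p under 0.05; DESeq2 called 2 genes, edgeR 0 and the block fit 1. Genes of 6 lists lay lower in OE1 than in OE2, with 0 members called: jasmonate (median -0.39, adjusted p = 5.1e-05, and adjusted p = 0.66 with an estimated correlation), abscisic acid (median -0.31, adjusted p = 3e-04, and adjusted p = 0.96 with an estimated correlation), seed storage (median -0.84, adjusted p = 9e-04, and adjusted p = 0.66 with an estimated correlation), heat shock (median -0.40, adjusted p = 0.0011, and adjusted p = 0.66 with an estimated correlation), rapid touch (median -0.45, adjusted p = 0.013, and adjusted p = 0.96 with an estimated correlation) and cytosolic ribosomal proteins (median -0.12, adjusted p = 0.03, and adjusted p = 0.96 with an estimated correlation). With the block the touch call was lost (adjusted p = 0.06) and the anthocyanin list was called (adjusted p = 0.036); with library size only the ribosomal call was lost (adjusted p = 0.061). Median, mean and test differed in sign for deadenylation, ethylene, iron and stomatal lists.

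The OE1 and OE2 fold changes resembled each other across genes. Of the called genes, 18 were higher in both lines and 2 lower in both, where independent lists would share 0.0355 and 0.00139. Across 21631 genes Pearson's r was 0.83 and Spearman's rho 0.71, with genes not being independent replicates. The lines share their WT libraries. In 100 simulations all libraries, controls included, were drawn as unchanged with each gene's spread and without batches. They gave r = 0.5, rho = 0.46 and 0 shared calls. With every gene drawn unchanged hardly any call could arise. That 0 therefore does not show how many shared calls the WT libraries bring. Batch differences, which libraries of the same batch share, entered the spread used in the simulations. The simulated covariance may therefore be too high and the differences from it too low. The covariance was 0.146 against a simulated 0.05, a difference of 0.096. For dne1 the difference was 0.0059 with OE1 and 0.0026 with OE2. With 3 shared controls these could not be split, so part of the excess of shared calls may come from them.

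The libraries labelled vcs-6 were compared with WT of batches 4 to 6, which asked what a changed decapping scaffold does to the transcriptome. Photosynthesis genes fell: 30 of the 31 measured members, with a median of -1.67. The photosystem I gene PSAD2 (AT1G03130) fell from 66140 ± 10900 to 11270 ± 1770, a change of -2.55 ± 0.18 (adjusted p = 4.6e-05), and the antenna gene LHCB4.2 (AT3G08940) changed by -2.39 ± 0.17. PORA (AT5G54190), an enzyme of chlorophyll synthesis, fell from 447.4 ± 92.9 to 4.78 ± 1.84. All 8 stomatal lineage markers fell, with SPCH (AT5G53210) at -3.03 ± 0.24, MUTE (AT3G06120) at -3.46 ± 0.32 and FAMA (AT3G24140) at -2.39 ± 0.15, the transcription factors of successive steps to guard cells.

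Camera called the photosynthesis list lower (adjusted p = 5.7e-12, and adjusted p = 0.87 with an estimated correlation) and the stomatal list lower (adjusted p = 4.6e-05, and adjusted p = 0.42 with an estimated correlation); adjusted over the list alone, 30 and 8 members fell. Markers of another organ did not move one way: of 14 root and root hair markers 3 rose and 3 fell (adjusted p = 0.79), with the nitrate transporter NRT2.1 at -3.58 ± 0.77 and PRP3 at 1.03 ± 0.30. RBCS2B, a Rubisco small subunit that fell by 3.41 ± 0.23, shares 37.1% of its 31-base words with its copies, and LHCB1.2, which fell by 2.61 ± 0.22, shares 25.1%; both values are uncertain.

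Heat shock genes rose: 15 of 18, with a median of 3.43. The small heat shock gene HSP17.6A (AT5G12030) rose from 112 ± 26.5 to 2432 ± 303, a change of 4.45 ± 0.19 (adjusted p = 8.7e-06), and HSP18.2 (AT5G59720) by 4.18 ± 0.18. The plastid chaperone gene HSP21 stood at 312 ± 38.9 against 1.08 ± 0.099 in WT (adjusted p = 6.5e-06). Phosphate starvation genes rose in 9 of 13 cases, among them the phosphatase gene PAP17 (2.96 ± 0.29) and the noncoding RNA AT4 (3.41 ± 0.37). Seed storage and embryo genes rose in 10 of 13 cases, with the late embryogenesis gene EM1 at 5.59 ± 0.44 and the oleosin gene OLEO2 at 2.93 ± 0.31.

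Of 22 cell cycle and shoot meristem genes 11 rose and 2 fell, with the mitotic kinase genes CDKB2;2 at 2.14 ± 0.12 and AUR1 at 1.35 ± 0.12, and 10 of 15 cytosolic ribosomal protein genes rose, RPS5A by 1.38 ± 0.12. Camera called these 5 lists higher: heat shock (adjusted p = 9.9e-08, and adjusted p = 0.42 with an estimated correlation), ribosomal proteins (adjusted p = 0.0068, and adjusted p = 0.87 with an estimated correlation), phosphate starvation (adjusted p = 0.011, and adjusted p = 0.87 with an estimated correlation), seed storage (adjusted p = 0.011, and adjusted p = 0.87 with an estimated correlation) and cell cycle (adjusted p = 0.025, and adjusted p = 0.88 with an estimated correlation). CDKB2;2, AUR1, PAP17 and OLEO2 overlap genes on the opposite strand. Adjusted over the list alone, no list's count of members in either direction moved by more than 2 in the libraries labelled vcs-6.

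Defence and hormone lists moved in both directions and were not called. Of 24 salicylic acid and defence genes 8 rose and 5 fell (adjusted p = 0.65). The pathogenesis-related gene PR2 (AT3G57260) rose from 47.8 ± 39.9 to 7086 ± 3800, and PR1 stood at 183 ± 116 against 0.326 ± 0.564 in WT (adjusted p = 6.5e-05). The regulator WRKY70 (AT3G56400) fell by 3.16 ± 0.13 and ACD6 by 3.19 ± 0.33. Jasmonate genes split into 5 that rose and 6 that fell of 20 (adjusted p = 0.26), with the storage protein gene VSP2 at -2.60 ± 0.27 and the aminotransferase gene TAT3 at 4.33 ± 0.37. Abscisic acid, cold and drought genes rose in 10 and fell in 5 of 28 cases (adjusted p = 0.18), RD20 by 2.96 ± 0.27. Of 10 ethylene genes 5 rose and 1 fell (adjusted p = 0.26). Of 26 auxin and phyllotaxis genes 5 rose and 12 fell (adjusted p = 0.18), with the efflux carrier gene PIN7 at -2.13 ± 0.22 and PLT7 at 2.53 ± 0.19. Rapid touch and wound genes counted 1 higher and 2 lower of 20 (adjusted p = 0.33), TCH4 at -2.49 ± 0.51.

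Developmental and metabolic lists were mixed as well. All 6 measured of the 12 flowering markers passed, 4 higher and 2 lower (adjusted p = 0.45): the flowering repressor FLC rose by 3.42 ± 0.26 and FUL fell by 2.93 ± 0.39. Among 28 mRNAs targeted by microRNAs 8 rose and 9 fell (adjusted p = 0.97), with CUC1 at 3.29 ± 0.25 and SPL15 at -2.46 ± 0.28; their median was -0.11 and their mean 0.03. Of 20 circadian clock genes 3 rose and 9 fell (adjusted p = 0.18), with LHY at 2.71 ± 0.38 and GI at -0.84 ± 0.09. Glucosinolate genes counted 1 higher and 5 lower of 12 (adjusted p = 0.26), anthocyanin and flavonoid genes 2 and 3 of 16 (adjusted p = 0.26), and iron deficiency genes 1 and 2 of 16 (adjusted p = 0.92). The iron uptake gene FRO2 fell by 2.19 ± 0.55, the biosynthetic regulator TT8 by 2.52 ± 0.41 and the aminotransferase gene BCAT4 by 1.37 ± 0.16.

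RNA decay genes shifted by smaller amounts. Of 18 decapping and decay genes 3 rose and 3 fell (adjusted p = 0.67): VCS itself and LSM1B (0.70 ± 0.14) rose, while the helicase gene RH6 (-0.52 ± 0.10) and the exonuclease gene XRN2 (-0.58 ± 0.12) fell. The exonuclease gene SOV rose by 1.45 ± 0.13, among 3 rises and 3 falls of 22 deadenylation, exosome and uridylation factors (adjusted p = 0.67). Small RNA factors counted 2 higher and 5 lower of 17 (adjusted p = 0.26), AGO2 at 1.16 ± 0.15 and RDR6 at -1.10 ± 0.11. DNE1 stood at 907.2 ± 75 against 890.5 ± 26.2 (adjusted p = 0.87).

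Among the largest falls by size in the libraries labelled vcs-6, AT4G22490, described as a lipid-transfer-type protein gene, fell from 6793 ± 2640 to 86.6 ± 28.2 (-6.26 ± 0.30). AT3G16670 fell by 6.70 ± 0.35 and the defensin-like gene AT3G05727 changed by -6.34 ± 0.43. Among the rises, PNP-A (AT2G18660), a natriuretic-like peptide gene, rose by 7.93 ± 0.43, the hydrolase gene AT5G24200 by 6.95 ± 0.32 and VIM5 by 6.91 ± 0.62. In all 10988 of 21351 genes passed, 5696 higher and 5292 lower, and 5295 of them changed by at least 1 on the log2 scale. With library size as the only scaling, the median of all genes shifted by 0.11 and 10769 genes were called, 6497 higher and 4272 lower. Leaving out 1 library at a time gave 8743 to 10097 genes.

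**Figure D2:**
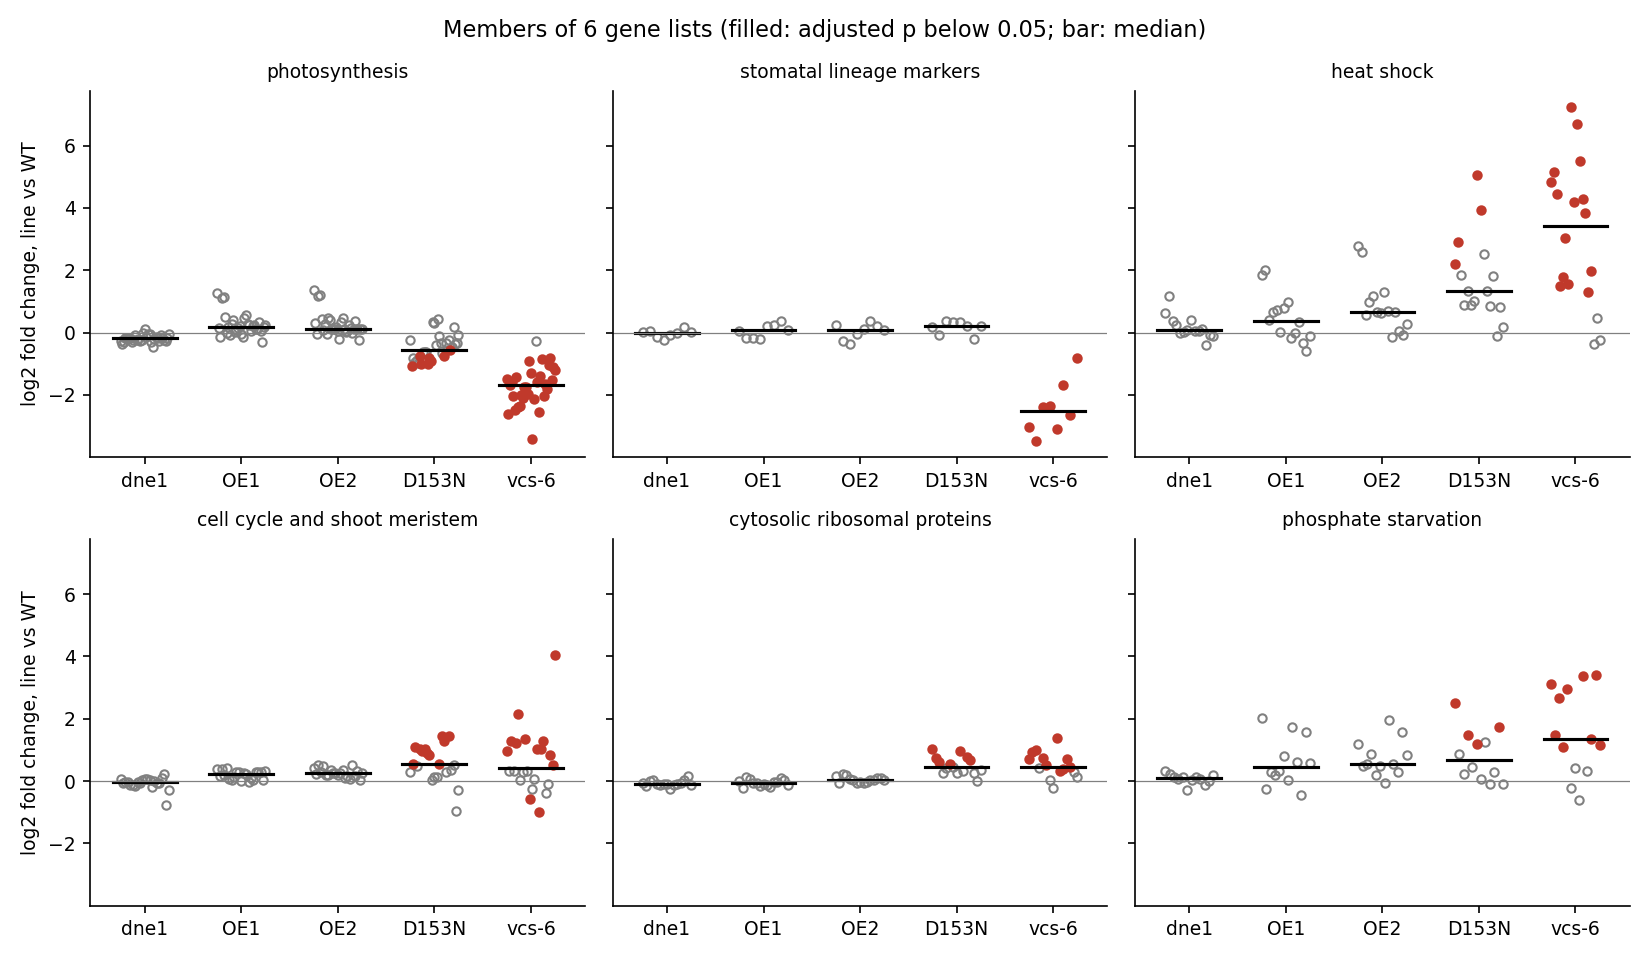
Log2 fold change of each measured member of 6 gene lists (points) in each line against its own WT, with the median as a bar; filled red points have an adjusted p below 0.05, and OE1 and OE2 share their WT libraries. The median of the photosynthesis list is -1.67 in the libraries labelled vcs-6 and -0.56 in the D153N line, and that of the heat shock list is 3.43 and 1.33.

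The line with the D153N substitution was compared with WT of batches 7 to 9, which asked what overexpression of the altered protein does. Cell cycle genes rose: 11 of 21 members and none lower, with the replication clamp gene PCNA2 (AT2G29570) up from 626.5 ± 24.6 to 1699 ± 68.3 (1.44 ± 0.08, adjusted p = 0.001) and CDKB2;1 up by 1.03 ± 0.15. Cytosolic ribosomal protein genes rose in 7 of 15 cases, RPS5A by 0.97 ± 0.09 and RPS6A by 1.02 ± 0.10. Heat shock genes rose in 4 of 16 cases, with HSP22 (AT4G10250) up from 9.80 ± 5.67 to 320.8 ± 41.7. Photosynthesis genes fell in 8 of 31 cases, with the antenna gene LHCA2 (AT3G61470) at -1.02 ± 0.17. Of 16 small RNA factors 6 fell, RDR6 by 0.78 ± 0.11 and DCL4 by 0.42 ± 0.10. With the batch as a block only 1 photosynthesis gene and 1 small RNA factor were called lower, while 9 cell cycle, 7 ribosomal and 5 heat shock genes were called higher.

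Camera called 12 lists in the D153N line. Those higher were ribosomal proteins (adjusted p = 4.1e-07, and adjusted p = 0.53 with an estimated correlation; 13 members adjusted over the list alone), cell cycle (adjusted p = 1.5e-05, and adjusted p = 0.51 with an estimated correlation; 14, and 1 lower), heat shock (adjusted p = 3.3e-05, and adjusted p = 0.51 with an estimated correlation; 9), abscisic acid (4 of 28 rose, adjusted p = 0.0015, and adjusted p = 0.66 with an estimated correlation; 6), phosphate starvation (4 of 12 rose, adjusted p = 0.021, and adjusted p = 0.66 with an estimated correlation; 4), flowering (1 of 11 rose, adjusted p = 0.038, and adjusted p = 0.51 with an estimated correlation; 3) and iron deficiency (0 of 17 called, adjusted p = 0.042, and adjusted p = 0.69 with an estimated correlation; 0). With library size as the only scaling the flowering (adjusted p = 0.059) and iron (adjusted p = 0.083) calls were lost, and defence (adjusted p = 0.034) and seed storage (adjusted p = 0.037) lists were called lower. The cold gene KIN1 rose by 1.72 ± 0.26, RD20 by 1.69 ± 0.29, the phosphate starvation RNA AT4 by 1.74 ± 0.38 and the flowering signal gene FT by 1.05 ± 0.25.

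Lists called lower were photosynthesis (adjusted p = 6.8e-05, and adjusted p = 0.66 with an estimated correlation; 11 members adjusted over the list alone), small RNA factors (adjusted p = 0.021, and adjusted p = 0.66 with an estimated correlation; 6), deadenylation and exosome factors (1 rose and 4 fell of 22, adjusted p = 0.021, and adjusted p = 0.51 with an estimated correlation; 1 and 7), microRNA targets (2 rose and 4 fell of 28, adjusted p = 0.021, and adjusted p = 0.51 with an estimated correlation; 2 and 7) and rapid touch genes (0 of 19 called, adjusted p = 0.024, and adjusted p = 0.69 with an estimated correlation; 0). The deadenylase scaffold gene NOT1 fell by 0.63 ± 0.12 and the exosome nuclease gene RRP44A by 0.59 ± 0.09. With the block 1 microRNA target was called higher and 1 lower. Among microRNA targets the superoxide dismutase gene CSD2 rose by 0.88 ± 0.14 and GRF1 fell by 0.55 ± 0.12.

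The 11 other lists were not called in the D153N line with the deposited scaling. Decapping genes counted 2 higher and 4 lower of 18 (2 and 6 adjusted over the list alone): LSM1B rose by 0.95 ± 0.10, and VCS and its relative VCR (-0.47 ± 0.09) fell. In the defence list PR5 rose by 2.44 ± 0.35 while WRKY70 fell by 1.94 ± 0.47 and RPP4, which shares 46.8% of its 31-base words with copies, by 1.05 ± 0.19. Among 8 measured seed storage genes CRU3 stood at 0.544 ± 0.943 against 81.1 ± 59.1 in WT (adjusted p = 0.011) and CRA1 fell by 4.56 ± 1.11. GI of the circadian list fell by 0.58 ± 0.10, JMT of the jasmonate list rose by 1.47 ± 0.32, F3H of the flavonoid list rose by 0.38 ± 0.10, NRT2.1 of the root list fell by 1.53 ± 0.39, and 2 auxin genes fell, ARF5 by 0.46 ± 0.12. No ethylene, glucosinolate or stomatal gene was called. Circadian, decapping and root lists differed in sign between median, mean and test.

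By size, AT5G35935 rose from 30.9 ± 16.3 to 2192 ± 416 (6.21 ± 0.36, adjusted p = 0.001) and AT1G75945 from 1.31 ± 1.52 to 303.5 ± 50.9, though AT1G75945 also stood at 417 in a WT library of batch 2 and at 201 in that of batch 6. AT3G42090 stood at 209 ± 40.2 against 0.248 ± 0.429 in WT (adjusted p = 0.00054). MRD1, which overlaps an opposite-strand gene, fell by 5.88 ± 0.27, from 1407 ± 67.2 to 24.3 ± 10.8, and stood at 32.9 to 61.7 in WT libraries of batches 1, 3 and 6. AT3G16670 fell by 2.04 ± 0.15. In total 3365 of 21124 genes passed, 1920 higher and 1445 lower, of which 591 changed by at least 1 on the log2 scale. The batch block gave 2125 genes, 1365 higher and 760 lower. With library size only, which shifted the median of all genes by 0.1, 2860 genes passed, 2171 higher and 689 lower.

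Both limits of the D153N result concern single libraries and transcript length. The count was 1356, 1107 and 754 without WT libraries 7, 8 and 9, and 1703 and 1142 without D153N libraries 14 and 15; 29 of 52 values named for this line lost their call in at least 1 such fit, LHCA2, NOT1, WRKY70, CDKB2;1 and VCS among them, and PCNA2, RPS5A, HSP22 and RDR6 did not. With the batch as a block 11 lost it: DCL3, DCL4, F3H, FT, GRF1, JMT, LHCB4.1, NRT2.1, PSAK, SPL3 and UPF3. Across genes, fold change fell with transcript length in the D153N line (Spearman's rho -0.41) and the libraries labelled vcs-6 (-0.24). It rose with length in dne1 (0.17) and hardly moved with it in OE1 (0.01) and OE2 (-0.05). With genes ordered by length in 10 equal bins, the shortest bin, with a median of 724.5 bases, had a median change of 0.37 in the D153N line and the longest, with a median of 3766.5 bases, -0.29. After removal of each library's trend on length and GC content 1469 genes were called, 903 higher and 566 lower.

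**Figure D3:**
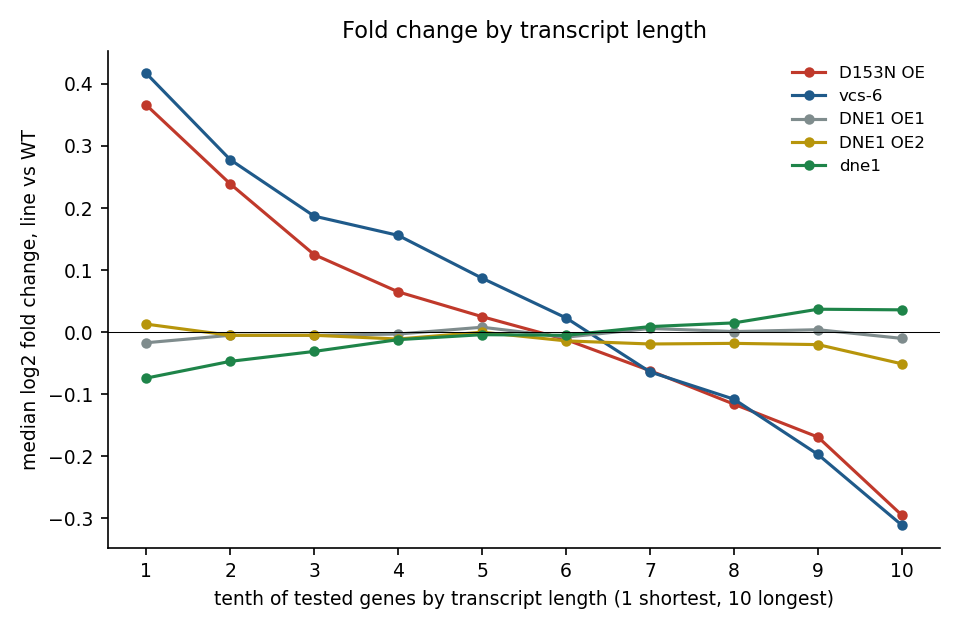
Median log2 fold change of each line against its own WT (vertical axis) in 10 equal bins of the tested genes ordered by transcript length (horizontal axis, 1 is the shortest). The D153N line runs from 0.37 to -0.29 and the libraries labelled vcs-6 from 0.42 to -0.31, while dne1 runs from -0.07 to 0.04.

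The D153N line and the lines with the wild-type form were compared by a difference of effects, each line against its own WT. A fit of all 24 libraries was used. The D153N form came from a single line, so the substitution cannot be told from other features of that line. The rise of DNE1 itself differed by 0.43 ± 0.18 (adjusted p = 0.24). PCNA2 changed by 1.4 ± 0.21 more in the D153N line (adjusted p = 0.0013), RPS5A by 1.05 ± 0.15 more, RPS6B by 0.87 ± 0.16 more and HSP22 by 3.81 ± 0.79 more. Among genes with a lower effect in the D153N line, CRK23 differed by -3.93 ± 0.78, RLP23 by -3.26 ± 0.83 and FLA5 by -2.40 ± 0.48. PLT7, a regulator of phyllotaxis, differed by -1.37 ± 0.34. HSP22, RLP23 and PLT7 lost their call in at least 1 fit that left out a library and in edgeR with deposited-type factors (adjusted p = 0.26, 0.062 and 0.052).

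A total of 475 of 22293 genes differed, 390 higher and 85 lower; the block gave 1012 (732 higher, 280 lower), DESeq2 988, and library size only 546 (523 higher, 23 lower). Since the D153N and wild-type forms were grown in different batch sets, the test rests on each set's own WT. Without a library of WT batches 1, 2 or 3 the count was 296, 242 or 862, without that of WT batches 7, 8 or 9 it was 260, 196 or 270, without D153N libraries 13, 14 or 15 it was 296, 197 or 276, and it was 309 without OE1 library 1 and 313 without OE2 library 2. Transcript length ran with this difference too (rho -0.39), and 286 genes were called with the length and GC trends removed, or 673 with the block as well.

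Lists called higher in the difference were ribosomal proteins (2 of 15 called, 4 adjusted over the list alone, adjusted p = 5.8e-06, and adjusted p = 0.58 with an estimated correlation), heat shock (1 of 18, 3 adjusted over the list alone, adjusted p = 0.0033, and adjusted p = 0.58 with an estimated correlation) and cell cycle (1 of 22, 4 higher and 2 lower adjusted over the list alone, adjusted p = 0.033, and adjusted p = 0.75 with an estimated correlation). Called lower were photosynthesis (0 of 31, median -0.75, adjusted p = 2e-05, and adjusted p = 0.6 with an estimated correlation), small RNA factors (adjusted p = 0.029, and adjusted p = 0.58 with an estimated correlation), microRNA targets (adjusted p = 0.031, and adjusted p = 0.6 with an estimated correlation), deadenylation factors (adjusted p = 0.04, and adjusted p = 0.58 with an estimated correlation), defence (adjusted p = 0.04, and adjusted p = 0.6 with an estimated correlation) and auxin (adjusted p = 0.047, and adjusted p = 0.58 with an estimated correlation). Adjusted over the list alone, 2 auxin genes, 3 microRNA targets and 1 small RNA factor were lower. With the block iron deficiency was called higher (adjusted p = 0.042), and with library size only the cell cycle (adjusted p = 0.073), deadenylation (adjusted p = 0.11) and small RNA (adjusted p = 0.053) calls were lost. Circadian and root lists differed in sign between median, mean and test.

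Effects in the libraries labelled vcs-6 were tested against those in the D153N line in the same way. Stomatal lineage genes set them apart: all 8 were lower in the effect of the libraries labelled vcs-6, with FAMA at -2.77 ± 0.25 and SPCH at -3.22 ± 0.40. Photosynthesis genes differed in 11 of 31 cases, all lower, among them PSAG at -1.42 ± 0.32. Some regulators of the shoot apex were higher while their lists were not called: STM at 1.80 ± 0.44 in the cell cycle and shoot meristem list (5 higher and 2 lower of 22, adjusted p = 0.93), PLT7 at 3.57 ± 0.37 in the auxin and phyllotaxis list (5 higher and 9 lower of 28, adjusted p = 0.57), and the boundary genes CUC1 and CUC2 at 4.21 ± 0.55 and 2.42 ± 0.40 among microRNA targets (8 higher and 4 lower of 28, adjusted p = 0.44). The small heat shock genes HSP18.2 and HSP17.6A differed by 3.18 ± 0.42 and 2.61 ± 0.75, FLC by 3.18 ± 0.50 and FUL by -3.83 ± 0.43.

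This difference reached the threshold for 5883 of 22293 genes, 2964 higher and 2919 lower in the libraries labelled vcs-6. Camera called the stomatal list lower (adjusted p = 1.1e-08, and adjusted p = 0.064 with an estimated correlation; 8 members adjusted over the list alone) and photosynthesis lower (adjusted p = 2.3e-06, and adjusted p = 0.83 with an estimated correlation; 14). It called ethylene (4 of 10 higher, adjusted p = 0.015, and adjusted p = 0.63 with an estimated correlation; 4), heat shock (4 of 18, adjusted p = 0.015, and adjusted p = 0.83 with an estimated correlation; 4) and seed storage (6 higher and 1 lower of 14, adjusted p = 0.015, and adjusted p = 0.83 with an estimated correlation; 9 and 1) higher. Cell cycle, ribosomal and small RNA lists differed in sign between median, mean and test.

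Genes called in both of these comparisons were counted per direction. Of 20836 genes tested in both, 1311 rose in both and 890 fell in both, where independent lists would share 487 and 366; the odds ratios were 8.23 and 5.49. Another 42 genes rose in the libraries labelled vcs-6 and fell in the D153N line, and 83 fell in the former and rose in the latter. Fold changes correlated across genes at r = 0.43 (rho = 0.45, covariance 0.248), and 67.5% had the same sign. The comparisons use different WT libraries. After removal of the length and GC trends 646 genes rose and 395 fell in both, and r was 0.41. D153N and both DNE1 overexpressors together shared 29 rises and 3 falls, against 5.6 and 0.482 for independent lists, and the block gave 108 and 17. The test of both DNE1 overexpressors together called 68 genes higher that were also tested in the libraries labelled vcs-6. Of these, 61 rose there (odds ratio 25.3), and of 7 lower genes 4 fell there (odds ratio 3.96, Fisher's exact p = 0.072). With the block for the overexpressors 304 of 423 rises were shared (odds ratio 7.72) and 32 went the other way, and 47 of 101 falls were shared (odds ratio 2.6) with 18 the other way.

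**Figure D4:**
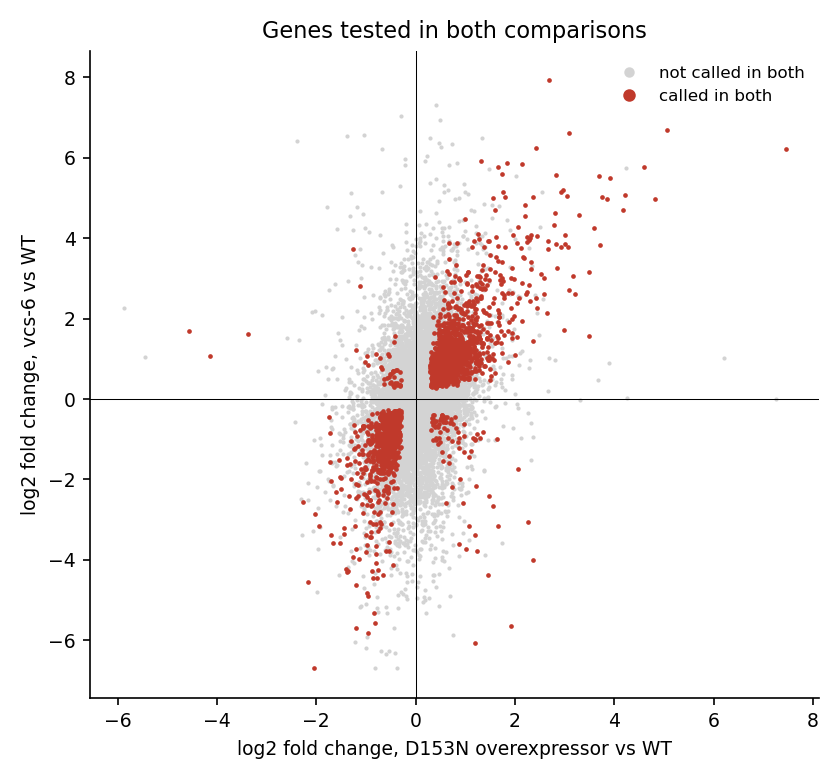
Log2 fold change against WT of the libraries labelled vcs-6 (vertical axis) and of the D153N line (horizontal axis), 1 point per gene tested in both; red points have an adjusted p below 0.05 in both. Red points gather at the upper right (1311 genes) and the lower left (890 genes).

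The authors' deposited table gives its own DESeq2 comparisons. At an adjusted p under 0.05 the authors' deposited table lists 15 genes for dne1, of which 3 are called here, 1349 for the DNE1 overexpressors, of which 79 are called here for both lines together, 4781 for D153N, of which 3176, and 12666 for vcs, of which 10758. Across genes the fold changes of the authors' deposited table correlated with those given here at r = 0.841, 0.867, 0.978 and 0.989.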

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

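The tests of length trends between libraries, WT variation, root markers and scaling below were chosen only after the results were seen; removal of the length and GC trend from the photosynthesis genes was written down before its result. Values are listed here when the test of a difference between effects called them.

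The D153N line and the wild-type DNE1 overexpressors differed in 475 genes and 9 gene lists, by the test of the difference itself. The largest differences were AT4G04223 at 4.70, HSP22 at 3.81, AT1G04533 at 3.17 and LEA7 at 3.17, higher in the D153N effect; AT3G29631 is given no value, since a group of it holds 3 or fewer reads. CRK23 differed by -3.93, RLP23 by -3.26, FLA5 by -2.40, AT5G34795 by -2.30 and CXE17 by -2.11. AT1G04533 and AT4G04223 share 45.3% and 50.1% of their 31-base words with other transcripts. At AT4G04223 all 6 WT libraries of other comparisons reached the level of OE1 and OE2, so variation among WT plants may account for its difference.

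The libraries labelled vcs-6 and the D153N line differed in 5883 genes and 5 lists. Higher in the effect of the former were ELI3-2 at 8.99, MRD1 at 8.16, PDF1.4 at 7.93 and SAG13 at 7.60. Lower were AT1G31690 at -7.57, AT1G75945 at -7.34, AT1G66100 at -7.29 and AT3G21950 at -6.64. PR1, called higher, and AT3G42090, called lower, are given no value for the same reason. At MRD1 and AT1G75945 1 WT library of another comparison reached the level of the D153N line, so variation among WT plants may account for a part there.

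In the D153N line and the libraries labelled vcs-6, short transcripts lay higher and long ones lower. The groups' mean slopes on log2 length differed by 4.33 times the widest range within a group for D153N and 2.2 times for the libraries labelled vcs-6. For D153N the difference was -0.242 and that range 0.056, but the range reached 0.141 in OE1 and its WT. Both differences exceeded every such range in size. With 3 libraries per group this does not exclude bias that varies from library to library. A length or GC trend as the whole cause is argued against for 1255 of the genes called in D153N, which stayed called after each library's trend was removed (median size 0.78 before and 0.69 after, SE 0.12 both times; with the batch as a block as well, 629 of the 3365 genes called in D153N were called), and for 82.4% of those in the libraries labelled vcs-6. For 2102 genes of D153N it cannot be told apart from a change of each gene, since their calls ended as the median size dropped from 0.53 to 0.31 at an SE of 0.11. RNA or library preparation that differed between a line and its WT stays open, as does a change in the plants that follows length.

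Some of the largest changes in dne1, the overexpressors and the D153N line lay in genes that also vary among WT plants. At 5 of 32 named genes (AT4G04223, AT3G55710, MRD1, AT1G75945 and AT2G06995) at least 1 of the 6 WT libraries of other comparisons reached the level of the line, so variation among WT plants may account for these. The genes had been chosen as separate from the WT libraries of their own comparison, so only the 6 others bear on this. At 27 genes none of the 6 reached the line. In 5 of these (IMS2, AAP2, AT5G03350, AT5G35935 and CRU3) the range of all 9 WT libraries was as large as the change, which leaves it open, and in 22 it was smaller, which argues against it there. What makes these genes vary was not tested, and a difference between seed stocks stays open.

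Photosynthesis and stomatal genes fell in the libraries labelled vcs-6. Among root markers 3 fell while 3 rose, which shows no common rise. Of all 21351 genes tested 5696 rose and 5292 fell, so counts this small cannot decide on less leaf and relatively more root in the sample, which stays open. The choice between the deposited scaling and library size is argued against, as 30 photosynthesis genes stayed lower with library size only. That scaling shifted the median of all genes by just 0.11, and neither scaling would show a change in total mRNA. A length or GC trend is argued against as well, with 30 lower after its removal. A change in the plants labelled vcs-6, including fewer green or guard cells or a different stage of development, stays open as an untested biological hypothesis, and so do preparation differences between the groups.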

How the results depend on the processing

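Tests chosen only after the data were seen were TMM for gene lists and shared calls, pseudocounts 0.5 and 5, removal of length and GC trends, batches 1 and 2 alone, and everything for both overexpressors together. Of 177 alternative values for counts that left out no library, 113 stayed within 1.5 times the reported one, as did 36 of 72 that left out a library. None of the 200 values of genes named by the rule and checked here, of which the text prints a part, reversed under the settings run; all 200 were called, and 144 stayed called in all that gave an adjusted p; DESeq2 gave no adjusted p for AT3G29631 and AT1G75945 in the differences of effects. Where no construction is named below, the cause was not tested. No paired analysis was possible because the deposited columns of vcs-6 carry no batch, which holds for its comparison with WT and its difference from D153N.

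With DESeq2 the counts were 7 for dne1, 200 for OE1, 168 for OE2, 329 for both lines together, 2 for OE1 against OE2 and 988 for D153N less wild-type DNE1. EdgeR gave 16 for OE1, 20 for OE2 and 51 for both with RLE factors, 14 and 51 for OE1 and both with library size only, and 17, 21 and 52 for OE1, OE2 and both with TMM. With library size only dne1 had 3 genes, 1 higher. A pseudocount of 0.5 gave 2 for dne1. With the replicate block the counts were 268 for OE1, 253 for OE2, 534 for both, 2125 for D153N, 1 for OE1 against OE2 and 1012 for D153N less wild-type DNE1. A minimum log2 change of 1, which can only lower a count, gave 5295 for vcs-6, 591 for D153N, 160 for D153N less wild-type DNE1 and 3531 for vcs-6 less D153N.

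In a fit of all 24 libraries OE1 and OE2 had 96 each, both together 195 and OE1 against OE2 had 1. With only the libraries compared dne1 had 2 and OE1 and OE2 had 10 each. All 9 WT libraries as a single control, which mixes batch sets, gave 434 for OE1, 299 for OE2 and 3493 for both. Batches 1 and 2 alone, with fewer libraries, gave 1 for dne1, 4 for OE1, 9 for OE2 and 17 for both. OE2 alone in place of both lines gave 240 for D153N less wild-type DNE1. Removal of length and GC trends gave 2 for dne1, 1469 for D153N and 286 for D153N less wild-type DNE1. With the block as well it gave 334 for OE1, 277 for OE2, 657 for both and 714 for D153N. It then gave 673 for D153N less wild-type DNE1 and 1 for OE1 against OE2.

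Shared calls of vcs-6 and D153N numbered 2201, and 353 with a minimum log2 change of 1 or 1041 with trends removed. Those of OE1 and OE2 numbered 20, and 117 with DESeq2 or 180 with the block. Those of D153N and both overexpressors numbered 32, and 124 with DESeq2, 21 with TMM or 125 with the block. With an estimated correlation between genes, 0 lists were called in each of the 9 comparisons.

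Leaving out each library in turn, counts ran from 2 to 7 for dne1, 10 to 31 for OE1, 5 to 35 for OE2, 14 to 73 for both, 8743 to 10097 for vcs-6, 754 to 4084 for D153N, 0 to 0 for OE1 against OE2, 196 to 862 for D153N less wild-type DNE1 and 4937 to 5790 for vcs-6 less D153N. The lowest were without dne1 library 2, OE1 library 1, OE2 library 1, WT library 1, vcs-6 library b, WT library 9, WT library 8 and WT library 7 in this order, OE1 against OE2 aside; the report names the others that moved a count by over 1.5 times. Among these 200 values, leaving out a library ended the call of 29 of 52 in D153N, 7 of 14 in D153N less wild-type DNE1, 8 of 11 in OE1, 8 of 12 in OE2, 2 of 4 in dne1 (ARP9 and AT1G64795), 2 of 77 in vcs-6 (ERF6 and PRP3) and 0 of 30 in vcs-6 less D153N. At this depth and 3 libraries per group, limma recovered 6%, 31.3% and 86.2% of simulated changes of 1.5, 2 and 4 times in dne1. For OE1 against OE2 the shares were 0%, 45.5% and 75.8%, so low counts of calls do not show that genes were unchanged. The counts were drawn without batch differences, which had entered the spread used. These shares therefore do not show what the batch block gains or loses. In the D153N design 10 unchanged genes were called, and 54 with a length trend added.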

Other observations

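The gene families, the splits and the comparison of D153N genes with the overexpressors below were chosen only after the results were seen, as were all tests in this part.

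In the libraries labelled vcs-6, genes of the proteasome rose in 35 of 56 cases and fell in 1, with a median of 0.50 (camera adjusted p = 3.5e-06, and adjusted p = 0.15 with an estimated correlation). Late embryogenesis abundant genes, which protect drying cells, rose in 30 of 44 cases (adjusted p = 5e-06, and adjusted p = 0.29 with an estimated correlation), and F-box genes, which pick proteins for degradation, rose in 124 and fell in 28 of 291 cases (adjusted p = 5.2e-05, and adjusted p = 0.29 with an estimated correlation). Disease resistance genes fell in 44 and rose in 7 of 106 cases (adjusted p = 0.00011, and adjusted p = 0.29 with an estimated correlation), and ended at adjusted p = 0.17 with the length and GC trend removed. Genes described as ribosomal proteins, organelle ones included, rose in 157 of 274 cases in the D153N line (adjusted p = 3.2e-30, and adjusted p = 0.18 with an estimated correlation) and in 78 with the trend removed. In the libraries labelled vcs-6 150 of 272 rose and 35 fell (median 0.49, adjusted p = 4.1e-06, and adjusted p = 0.52 with an estimated correlation); with the trend removed 79 rose and 51 fell, the median was 0.11 and the call ended (adjusted p = 0.17).

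Cysteine-rich receptor-like kinase genes rose in 3 of 14 cases in both DNE1 overexpressors together (median 0.75, adjusted p = 1.1e-07, and adjusted p = 0.065 with an estimated correlation). Genes described as receptor-like proteins, kinases included, rose in 6 of 141 cases (adjusted p = 4e-06, and adjusted p = 0.2 with an estimated correlation), or 14 with 2 lower with the block. Both families also lay higher in dne1 against the same 3 WT libraries (medians 0.56 and 0.06, adjusted p = 4.3e-06 and 0.0021, and adjusted p = 0.13 and 0.52 with an estimated correlation), so these WT libraries may account for a part. Both families lay lower in the effect of D153N than in that of wild-type DNE1 (adjusted p = 6.4e-06 and 3.5e-11, and adjusted p = 0.044 and 0.023 with an estimated correlation). In the D153N line itself the cysteine-rich kinases had a median of -0.09 (camera adjusted p = 0.29). That was over 9 measured members, against 14 in the overexpressors and 17 in the difference, so the medians cover different members. Much of their difference may come from the rise against WT of batches 1 to 3 that dne1 shows as well. A difference between the constructs cannot be told from those WT libraries. The receptor-like proteins also fell in the D153N line itself (median -0.23, 1 higher and 19 lower of 136, adjusted p = 0.00022, and adjusted p = 0.18 with an estimated correlation), against a median of 0.14 in the overexpressors, so those WT libraries do not account for the whole of their difference; with the length and GC trend removed this fall was not called (adjusted p = 0.23).

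A hypothesis was that the rise of proteasome genes in the libraries labelled vcs-6 came from the length or GC trend between libraries. After its removal 26 of the 35 were called higher again, which argues against the trend as the whole cause, while the family's median fell from 0.50 to 0.27, so it may account for a part; a coordinated response of the plants may lie behind it, as an untested hypothesis.

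Another hypothesis was that the D153N and wild-type constructs act the same way on the genes called in D153N. Of 3341 such genes tested in batches 1 to 3, 71.5% had the same sign in both overexpressors, and 43.7% in dne1. Among 27 splits that part the batches 6 gave as high a percent, and others ran from 16.1 to 84.1, so the constructs cannot be told apart from differences between libraries by this test.

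Other splits of the same libraries were counted for each result. With 10 splits of 6 libraries a share under 0.05 cannot be reached. As many genes as the real split gave came from 1 of 10 splits for dne1 (4, highest other 0), OE1 (30, highest other 0), OE2 (37, highest other 0), vcs-6 (10988, highest other 0), D153N (3365, highest other 2) and vcs-6 less D153N (8803 with each WT mean subtracted, highest other 0), and from 10 of 10 for OE1 against OE2 (0 by limma with 152 at an unadjusted p under 0.05, highest other 0). As many lists came from 10 splits for dne1 (4, highest other 13), 9 for OE1 (5, highest other 11), 6 for OE2 (8, highest other 14), 6 for vcs-6 (7, highest other 15), 3 for D153N (12, highest other 12), 8 for OE1 against OE2 (6, highest other 12) and 9 for vcs-6 less D153N (5, highest other 13). In the designs with batch pairs, the 3 other splits that part all pairs gave at most 0 genes, and at most 5, 6, 8, 12 and 6 lists for dne1, OE1, OE2, D153N and OE1 against OE2.

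For both overexpressors as a single group against WT, 2 of 84 splits gave as many genes as the real one (91). The test that kept each line as its own group called 79. Libraries of the same batch resemble each other, so the 84 splits are not equivalent. This share therefore does not exclude chance, and the comparison was chosen after the data were seen. The highest other, 1812, was the split that sets the libraries of batch 3 against the rest, several times the real count, which points to a batch structure; the blocked count was 534, and the 26 others that part the batches gave at most 1. As many lists came from 50 of 84 splits (7, highest other 13), so chance cannot be excluded for the lists. For D153N less wild-type DNE1, with each WT mean subtracted, 1 of 84 splits gave as many genes (3950, highest other 7) and 37 of 84 as many lists (8, highest other 12). The error of a WT mean shifts all libraries of its lines alike, so the real split alone collects it, and this count says nothing on chance, here or for vcs-6 less D153N. The fit that carries the spread of WT called 475 genes, and the batch sets and the single D153N line stay confounded with the constructs.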
